A study of Homo sapiens with 16 samples.

How the data were processed

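The values come from the submitters' deposited array table of the series, which holds 54613 probe sets on 16 Affymetrix 3-prime arrays. Per the labels, cells of the pancreatic cancer line MIA PaCa-2 received 2.5 µM PP242, an inhibitor of the mTOR kinase, or DMSO vehicle for 12 hours. Cytosolic RNA and RNA from pooled gradient fractions with more than 3 ribosomes per mRNA, taken from a 10% to 50% sucrose gradient and isolated with Trizol, were labelled with biotin with the 3-prime IVT Express kit. Each of the 4 groups (cytosolic vehicle, polysome vehicle, cytosolic PP242, polysome PP242) has 4 replicates. Summarization was by RMA per the submitters' processing notes, with the version not stated. The deposited values are on the log2 scale, between 1.65 and 14.61, rounded to 2 decimals, with 0 missing. Background correction settings, whether arrays were normalized together, and the statistical model of the submitters are not given in the sources used here.

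The 8 cytosolic and the 8 polysome arrays look normalized apart from each other. The median spread of matching quantiles is 0.09 among cytosolic arrays and 0.07 among polysome arrays but 0.4 over all 16, and array medians run from 5 to 5.05 in cytosolic and from 4.57 to 4.63 in polysome RNA. A treatment effect is computed inside a pool and is relative to the other mRNAs of that pool. A loss of mRNA from polysomes shared by all genes is therefore not visible, and polysome over cytosolic levels depend on the scale chosen.

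Probe sets were mapped with the gene table given for the array. Of them, 41091 list 1 gene and were used, 1801 list several genes, and 11721 are not in that table. For the 10523 genes with more than 1 probe set, the probe set with the highest mean over all arrays stands for the gene, leaving 19777 genes. Control probe sets number 0.

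Testing used limma 3.58.1 in R 4.3.3, with statmod 1.5.0 for blocking. lmFit fitted 1 mean per group over all 16 arrays, and eBayes with an intensity trend moderated the variances. P-values are two-sided and adjusted with the Benjamini-Hochberg procedure over all genes, and a gene was called at an adjusted p under 0.05. Errors printed after ± are standard errors of the limma contrast unless SD is named. The 4 contrasts are PP242 against vehicle in polysome RNA, PP242 against vehicle in cytosolic RNA, the difference of these 2 effects (the effect on polysome association), and polysome over cytosolic RNA in vehicle-treated cells. Genes were also sorted by mode. The abundance mode is both pools called with the same sign and polysome association not called. The translation mode is the polysome effect and the association effect called with the same sign. The offset mode is the cytosolic effect called, the association effect called with the opposite sign, and the polysome effect not called. The association effect was also tested with each culture as a block, and by a regression per gene of polysome on cytosolic values with treatment as a term.

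Gene lists were fixed before the values were seen and tested with limma camera at a preset inter-gene correlation of 0.01, two-sided, adjusted over the 36 lists within each contrast. They cover the cytosolic and mitochondrial ribosomal proteins, other mRNAs with a 5-prime terminal oligopyrimidine (TOP) motif, complex I, ATP synthase, mitochondrially encoded RNAs, mRNAs described as eIF4E-sensitive, initiation factors, ribosome biogenesis, aminoacyl-tRNA synthetases, proteasome, mTOR components, cholesterol, fatty acid, purine and pyrimidine synthesis, glycolysis, hypoxia, ATF4, lysosome, autophagy, FOXO, ERK, NF-kB, interferon, p53, heat shock, endoplasmic reticulum chaperones, S phase, mitosis, homologous recombination, epithelial-mesenchymal transition, non-coding RNAs, and marker lists of fibroblasts, leukocytes, endothelium and normal pancreas. Each was tested again with the correlation estimated from the data and with fry, a self-contained test. A panel of single genes tied to mTOR was fixed as well, of which 28 are reported; the others are not reported here.

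Genes are named by a rule set in advance: for each contrast the 8 largest rises and 8 largest falls among called genes whose groups do not overlap, up to 4 members with the smallest p of each called list, and the panel. Other genes in the closing section were picked after the values were seen.

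Replicate numbers were checked as pairs. Deviations from the group mean correlated at above 0.1 in 16 of 16 pairs of arrays with the same number from different groups (0.164 to 0.510), and 13 of them matched their own number best. The numbers therefore pair samples, and results with the number as a block are printed beside the others where they differ. The labels do not state whether replicates are separate cultures, so p-values may measure only the spread between samples.

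The steps were tested on simulated data, with 50 genes planted at each size among 19777. At log2 0.5, 1, 1.5 and 2 the recovered share was 52, 92, 96 and 100% in polysome RNA, 40, 98, 100 and 100% in cytosolic RNA, and 4, 72, 92 and 100% for polysome association. Of 19337 unchanged genes 6 were called in polysome RNA, 40 in cytosolic RNA, 7 for polysome association and 0 at baseline. The 40 false cytosolic calls stood beside 20, 49, 50 and 50 recovered cytosolic genes at these sizes. Their share of the cytosolic calls was thus larger than the adjusted p threshold allows. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.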

Results

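PP242 blocks the kinase mTOR, whose complex 1 phosphorylates the translation repressor 4E-BP1 and the S6 kinases. The series profiles MIA PaCa-2 pancreatic cancer cells after 12 hours of 2.5 µM PP242 or DMSO, in cytosolic RNA and in RNA carrying more than 3 ribosomes, with 4 arrays in each of 4 groups. The questions are which mRNAs changed on polysomes, which changed in the cytosol, and which changed in polysome association. Arrays within a group correlate at 0.972 to 0.997. The first principal component (47.1% of variance) parts the polysome from the cytosolic arrays and the second (25.4%) parts PP242 from vehicle. The cytosolic PP242 arrays are the noisiest: the median SD of a gene is 0.245 there, against 0.122 in cytosolic vehicle, 0.159 in polysome vehicle and 0.147 in polysome PP242. Cytosolic PP242 arrays 2 and 4 get the lowest array weights, 0.360 and 0.251. Replicate numbers 1 and 2 also differ from 3 and 4 in all groups, so counts within each of these pairs of numbers are printed beside the pooled ones.

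Which mRNAs changed in amount on polysomes? PP242 lowered polysome-associated mRNAs of DNA replication and cell division. MCM10, a replication initiation factor, fell by 2.79 ± 0.28 on the log2 scale (n = 4 per group, adjusted p = 1.40e-06), from a mean of 8.85 (SD 0.32) to 6.06 (SD 0.54). CDC6, which loads the replicative helicase, fell by 2.67 ± 0.19, and CDK1, the mitotic kinase, fell by 2.25 ± 0.20. ID2, a repressor of helix-loop-helix transcription factors, showed -2.71 ± 0.21, EXO1, a DNA repair exonuclease, -2.46 ± 0.19, E2F8, an atypical E2F repressor, -2.43 ± 0.14, ZNF367 -2.39 ± 0.37, and GINS2, part of the replicative helicase, -2.33 ± 0.18. The largest rises were ELMOD1, a GTPase-activating protein, at 2.80 ± 0.28, the stromelysin MMP10 at 2.52 ± 0.23 and the oxytocin receptor OXTR at 2.43 ± 0.39. They were followed by S100A2 (2.27 ± 0.59), ROBO4 (2.25 ± 0.25), the kinase-like scaffold TRIB1 (2.12 ± 0.18), the antisense RNA TLR8-AS1 (2.07 ± 0.31) and HBEGF, a ligand of the EGF receptor (1.98 ± 0.29).

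In polysome RNA 2644 of 19777 genes passed, 1348 higher and 1296 lower, and 1589 of them by at least 1.5-fold (788 higher, 801 lower). With the replicate number as a block 4020 genes passed (2097 higher, 1923 lower). Within numbers 1 and 2 alone 2006 passed and within 3 and 4 alone 1089, and leaving out replicate 1 or 2 gave 1689 and 1627. The groups do not overlap for 3823 genes (19.3%, with 2.86% due to chance). The median of all genes moved by -0.005.

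**Figure D1:**
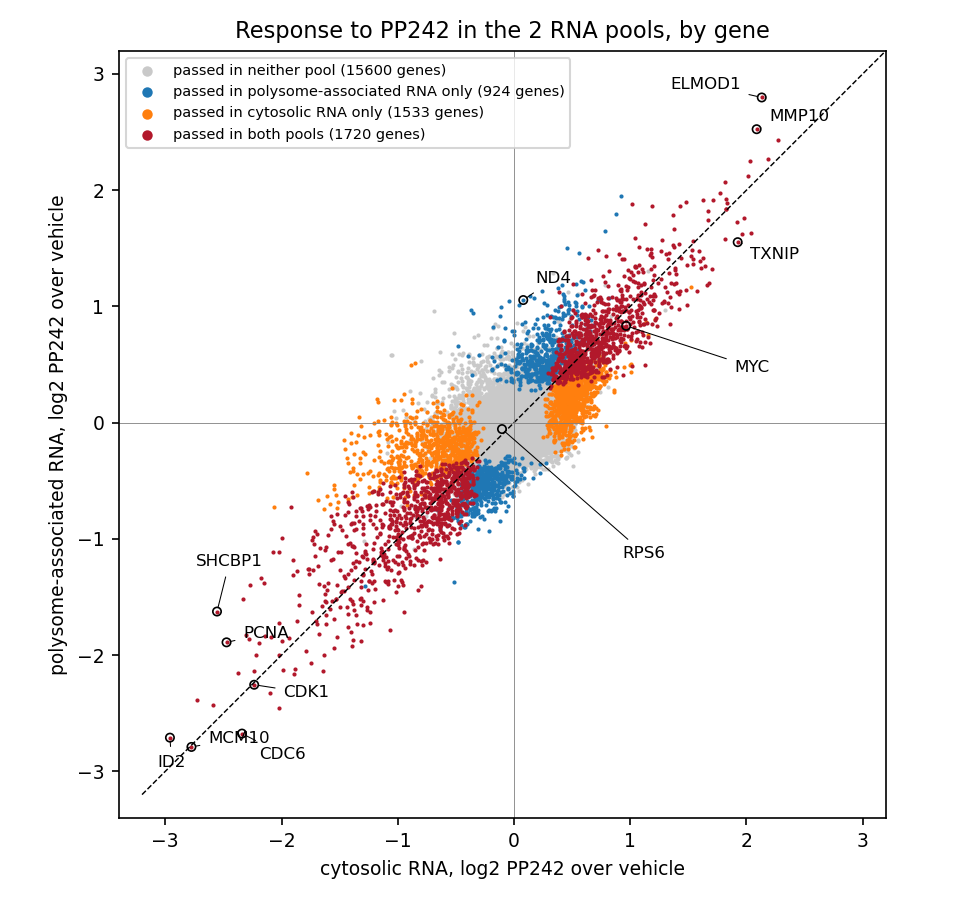
Log2 change after PP242 in cytosolic RNA against polysome-associated RNA, one point per gene, coloured by the pools in which the gene passed at an adjusted p under 0.05.

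Cell-cycle lists fell most on polysomes, and ERK feedback genes rose. Of 40 measured S-phase and DNA replication genes 38 fell and 2 did not pass (39 fell adjusted over the list alone), with a median of -1.59. RFC5 (-1.84 ± 0.10), RFC4 (-1.73 ± 0.11) and POLE2 (-2.13 ± 0.13) are among them, as is TYMS, the thymidylate synthase (-1.55 ± 0.11). Of 41 mitosis genes 40 fell (41 over the list alone), median -1.08, with the kinases AURKA (-1.53 ± 0.12), BUB1B (-1.36 ± 0.11) and BUB1 (-1.31 ± 0.11). Of 29 homologous recombination and Fanconi genes 18 fell, 1 rose and 10 did not pass (18 and 1 over the list alone), median -0.87, with RAD51AP1 (-2.0 ± 0.14), RAD54L (-1.87 ± 0.16) and BRCA1 (-1.48 ± 0.14). Of 20 ERK feedback genes 9 rose and 11 did not pass (14 rose over the list alone), median 0.57. They include the immediate-early factor EGR1 (1.67 ± 0.18), SPRY4 (1.32 ± 0.13), the ERK phosphatase DUSP6 (1.19 ± 0.18) and EPHA4 (0.72 ± 0.13). Camera gave adjusted p-values of 9.34e-60, 3.32e-41, 7.46e-17 and 3.31e-09, and these 4 calls hold with an estimated correlation (0.00497, 0.001, 0.00819 and 0.00292). They are the only list calls of either pool that do, and none holds for polysome association or for the baseline.

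Lists of amino acid, nucleotide, sterol, fatty acid, proteasome and heat shock genes moved down on polysomes by smaller amounts, with only part of each list passing. Of 32 ATF4 and amino acid response genes 12 fell, 2 rose and 18 did not pass (18 fell and 2 rose over the list alone), median -0.53, adjusted p = 0.213 with an estimated correlation. The serine synthesis enzymes PSAT1 (-1.87 ± 0.25) and PHGDH (-0.97 ± 0.16) fell, as did the lipoprotein receptor VLDLR (-0.96 ± 0.12). Of 17 cytosolic aminoacyl-tRNA synthetases 9 fell (12 over the list alone), median -0.51, with WARS1 (-0.91 ± 0.14) and AARS1 (-0.78 ± 0.14), adjusted p = 0.2 with an estimated correlation. Of 26 purine and pyrimidine synthesis genes 13 fell (15 over the list alone), median -0.40, adjusted p = 0.115 with an estimated correlation. PRPS1 (-1.20 ± 0.15), PAICS (-0.83 ± 0.11) and the mitochondrial folate enzyme MTHFD2 (-1.24 ± 0.22) belong to it. Of 31 proteasome subunits 14 fell (17 fell and 1 rose over the list alone), median -0.39, with PSMD12 (-0.70 ± 0.11) and PSMA2 (-0.67 ± 0.11), adjusted p = 0.213 with an estimated correlation. Of 20 cholesterol genes 9 fell (9 over the list alone), median -0.25, with ACAT2 (-1.62 ± 0.13), INSIG1 (-1.41 ± 0.21) and FDPS (-0.79 ± 0.11), adjusted p = 0.101 with an estimated correlation. Of 15 fatty acid synthesis genes 4 fell (5 over the list alone), median -0.21, adjusted p = 0.192 with an estimated correlation and 0.0903 without replicate 4. Of 18 heat shock genes 5 fell and 1 rose (7 and 1 over the list alone), median -0.25, with the co-chaperone BAG3 at -0.69 ± 0.12, adjusted p = 0.213 with an estimated correlation.

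Mitochondrial and translation machinery lists also moved down on polysomes. Of 75 mitochondrial ribosomal proteins 24 fell (33 over the list alone), median -0.32, among them MRPL48 (-0.68 ± 0.11) and MRPL46 (-0.61 ± 0.12), adjusted p = 0.218 with an estimated correlation. Of 16 ATP synthase subunits 5 fell (6 over the list alone), median -0.23, with ATP5MC1 at -0.80 ± 0.15, adjusted p = 0.253 with an estimated correlation. Of 33 complex I subunits 2 fell (2 over the list alone), median -0.19, and of 58 ribosome biogenesis factors 9 fell (9 over the list alone), median -0.17, with PNO1 at -0.74 ± 0.14. Both have adjusted p = 0.512 with an estimated correlation. Of 28 initiation factors 8 fell (8 over the list alone), median -0.20, with EIF2S2 at -0.71 ± 0.16, adjusted p = 0.218 with an estimated correlation. Of 23 mRNAs described as eIF4E-sensitive 5 fell and 2 rose (6 and 3 over the list alone), median -0.17, with RRM2, a ribonucleotide reductase subunit, at -1.94 ± 0.14 and cyclin CCND3 at -1.17 ± 0.13. Its adjusted p = 0.490 with an estimated correlation, and 0.0622 without replicate 3.

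Lists called higher on polysomes beyond ERK feedback were receptor feedback, lysosome, autophagy and epithelial-mesenchymal transition genes and mitochondrially encoded RNAs. Of 34 FOXO and receptor feedback genes 13 rose and 1 fell (14 and 2 over the list alone), median 0.27, adjusted p = 0.115 with an estimated correlation. KLF6 (1.20 ± 0.11), the insulin receptor substrate IRS2 (1.07 ± 0.13), BCL6 (0.91 ± 0.12) and the receptor IGF1R (0.98 ± 0.13) rose. Of 41 lysosome genes 9 rose and 3 fell (15 and 5 over the list alone), median 0.27, with the protease CTSL (1.14 ± 0.15) and PSAP (0.60 ± 0.11), adjusted p = 0.447 with an estimated correlation. Of 35 autophagy genes 8 rose and 1 fell (10 and 3 over the list alone), median 0.18, with the cargo receptor SQSTM1 (1.04 ± 0.16) and WIPI1 (0.94 ± 0.19), adjusted p = 0.218 with an estimated correlation. Of 24 epithelial-mesenchymal transition genes 6 rose (7 over the list alone), median 0.11, adjusted p = 0.103 with an estimated correlation. They mix the epithelial keratin KRT19 (1.13 ± 0.15) with ZEB1 (1.21 ± 0.23), a repressor of epithelial genes. Of 7 mitochondrially encoded RNAs 4 rose (6 over the list alone), median 0.81, with the complex I subunit ND4 (1.06 ± 0.17) and the cytochrome oxidase subunit COX2 (0.81 ± 0.16), adjusted p = 0.218 with an estimated correlation.

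Ribosomal protein mRNAs, the classic targets of mTOR in translation, did not pass the test on polysomes. Of 53 cytosolic ribosomal protein genes 0 passed by limma (0 over the list alone), median -0.03, camera adjusted p = 0.779. Their list mean was 13.17 (SD 0.04) in vehicle and 13.16 (SD 0.04) after PP242, high on the scale, so a change can be understated. Under cyclic loess between all arrays the median turns to 0.13 and 9 genes are called higher. Of 27 other 5-prime TOP mRNAs 1 fell (1 over the list alone), median -0.07, adjusted p = 0.5, and 0.06 with 4 higher under cyclic loess. The elongation factor EEF2 had 0.30 ± 0.10 (adjusted p = 0.0687, or 0.0230 with the replicate block), RPS6 -0.06 ± 0.12, and PABPC1 0.13 ± 0.08. The non-coding RNA list came close at adjusted p = 0.0612 (0.0172 with the replicate block). Further lists not called are glycolysis (0.0897), endoplasmic reticulum chaperones (0.124), NF-kB (0.209), interferon (0.617), hypoxia (0.779), p53 targets (0.892) and mTOR components (0.922). Marker lists of cell types other than the cancer cell were not called either: endothelium 0.282, fibroblasts 0.424, leukocytes 0.424 and normal pancreas 0.675.

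Of the 28 measured panel genes, 4 rose on polysomes, 6 fell and 18 did not pass. MYC (0.83 ± 0.15), IRS2, SQSTM1 and TXNIP (1.55 ± 0.38), a brake on glucose uptake, rose. The asparagine synthetase ASNS (-1.51 ± 0.28), the mTOR inhibitor DDIT4 (-1.57 ± 0.32), LDHA (-0.68 ± 0.11), CCND3, EIF4E (-0.59 ± 0.14) and TFAM (-0.45 ± 0.13) fell. The calls of TXNIP, EIF4E and TFAM are lost when a replicate is left out: adjusted p = 0.0506 without replicate 4, 0.0532 without replicate 2 and 0.204 without replicate 1. EIF4E also does not pass with the mean of its probe sets (-0.18, adjusted p = 0.427). Cyclin CCND1 (-0.26 ± 0.18, adjusted p = 0.464) and HIF1A (-0.20 ± 0.17, adjusted p = 0.552) did not pass.

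**Figure D2:**
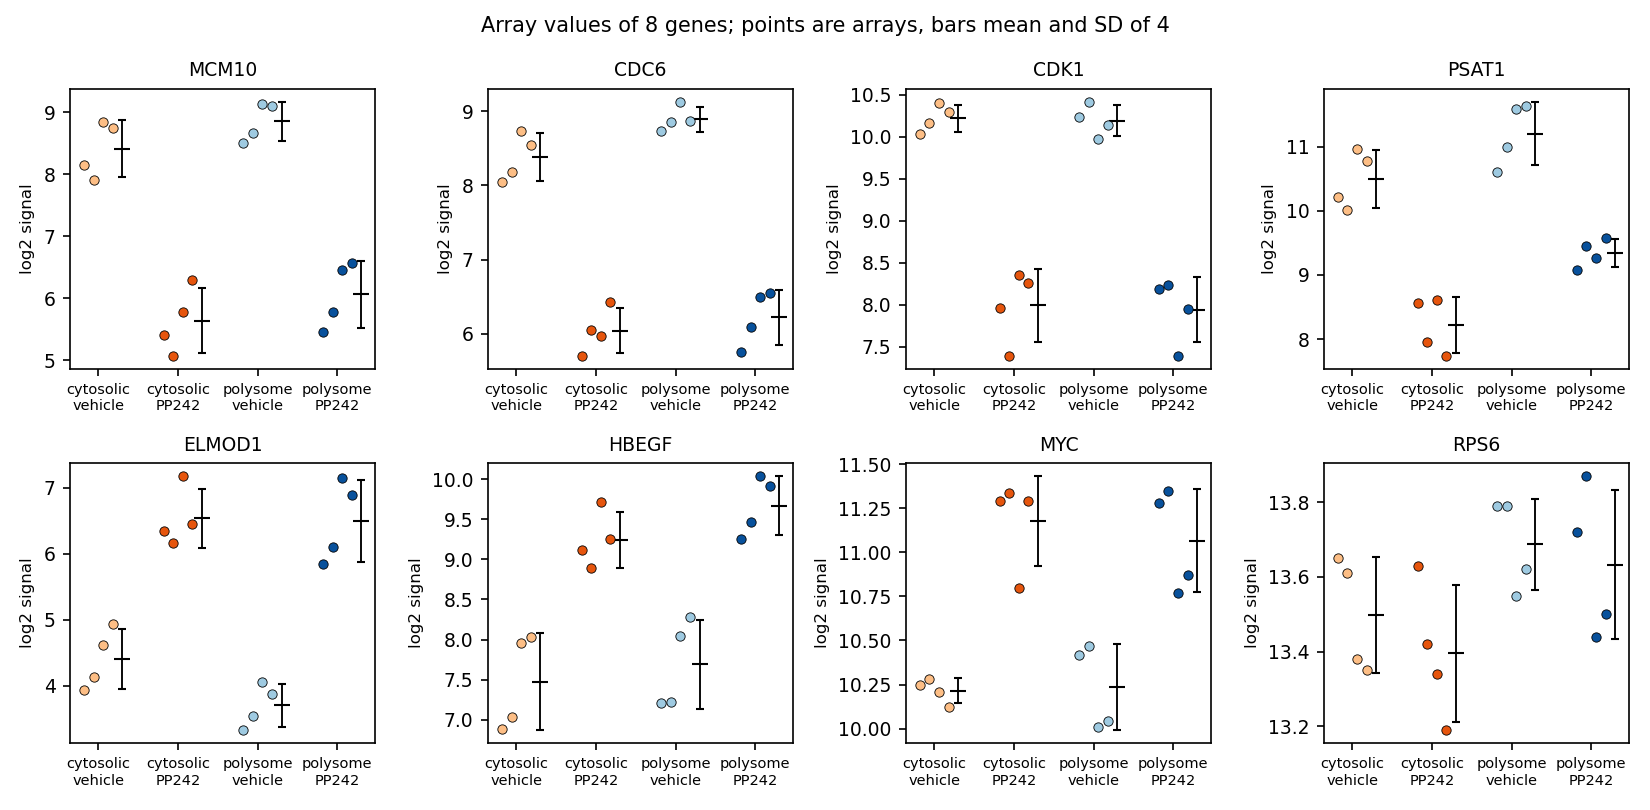
Log2 values of 8 genes in each of the 16 arrays, with the mean and SD of the 4 arrays of a group.

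Which mRNAs changed in the cytosol? The same replication and division genes fell in cytosolic RNA. ID2 fell by 2.96 ± 0.21 (n = 4 per group, adjusted p = 2.59e-08), MCM10 fell by 2.78 ± 0.28 and ZNF367 fell by 2.73 ± 0.37. E2F8 followed with -2.59 ± 0.14, SHCBP1, a midbody protein, with -2.56 ± 0.28, the sliding clamp PCNA with -2.47 ± 0.16, the S-phase cyclin CCNE2 with -2.38 ± 0.19 and CDC6 with -2.34 ± 0.19. The fit shares 1 spread per gene over all groups, and cytosolic PP242 is the noisiest, so errors of cytosolic effects can be too small. SHCBP1, for example, has an SD of 0.16 in cytosolic vehicle and 0.86 in cytosolic PP242. OXTR (2.27 ± 0.39), S100A2 (2.19 ± 0.59), ELMOD1 (2.13 ± 0.28) and MMP10 (2.09 ± 0.23) rose most, then the long non-coding RNA BLACAT1 (2.04 ± 0.16), ROBO4 (2.03 ± 0.25), TRIB1 (2.01 ± 0.18) and the surface protein CDCP1 (1.98 ± 0.23). The S100A2 call is lost without replicate 2 (adjusted p = 0.0627) or 4 (0.0683). S100A2 also lay 1.74 higher in numbers 1 and 2 than in 3 and 4, which the fit without a block leaves in its error. Cytosolic vehicle signals of ELMOD1 (mean 4.405), MMP10 (3.71) and BLACAT1 (4.73) lie low on the scale, so their rises are not exact sizes.

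In cytosolic RNA 3253 genes passed, 1689 higher and 1564 lower, and 1837 by at least 1.5-fold (788 higher, 1049 lower). With the replicate block 4929 passed (2755 higher, 2174 lower). Within numbers 1 and 2 alone 2450 passed and within 3 and 4 alone 1058. Without replicate 2 the count was 1543 (658 higher, 885 lower), without replicate 4 1604 (686 higher, 918 lower), without cytosolic PP242 arrays 2 and 4 1976 (672 higher, 1304 lower), and with only the 8 cytosolic arrays 2069. On simulated data the cytosolic fit made more false calls than the adjusted p threshold allows. The count of 3253 may thus hold more false calls than that threshold states. The groups do not overlap for 3496 genes (17.7%, with 2.86% due to chance). The median of all genes moved by 0.04.

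Cell-cycle lists led in the cytosol as well. Of the S-phase genes 39 of 40 fell (39 over the list alone), median -1.39, with RFC4 (-1.69 ± 0.11) and TYMS (-1.61 ± 0.11), camera adjusted p = 6.28e-51 and 0.00846 with an estimated correlation. Of the mitosis genes 40 of 41 fell (41 over the list alone), median -1.20, with cyclin CCNA2 (-1.76 ± 0.16) and BUB1 (-1.30 ± 0.11), adjusted p = 8.81e-04 with an estimated correlation. Of the homologous recombination genes 18 fell and 1 rose (21 and 1 over the list alone), median -1.0, with RAD51AP1 (-2.22 ± 0.14) and BRCA1 (-1.85 ± 0.14), adjusted p = 0.00846 with an estimated correlation. Of the ERK feedback genes 11 of 20 rose (11 over the list alone), median 0.57, with SPRY4 (1.39 ± 0.13), EGR1 (1.38 ± 0.18) and EPHA4 (1.01 ± 0.13), adjusted p = 0.00846 with an estimated correlation.

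Of the lysosome genes 19 of 41 rose in the cytosol and 3 fell (22 and 3 over the list alone), median 0.41, adjusted p = 0.429 with an estimated correlation. CTSL (1.48 ± 0.15), the hexosaminidase HEXA (1.17 ± 0.14) and PSAP (0.89 ± 0.11) rose. Of the FOXO list 11 of 34 rose (16 rose and 1 fell over the list alone), median 0.34, with KLF6 (1.35 ± 0.11) and the receptor ERBB2 (1.08 ± 0.14), adjusted p = 0.268 with an estimated correlation. Of the epithelial-mesenchymal list 7 of 24 rose (8 over the list alone), median 0.15, with the keratin KRT19 (1.57 ± 0.15) and the matrix protein TGFBI (1.34 ± 0.15), adjusted p = 0.0809 with an estimated correlation. Of the ATF4 list 12 fell and 3 rose (12 and 3 over the list alone), median -0.20, with PSAT1 (-2.28 ± 0.25) and VLDLR (-1.16 ± 0.12), adjusted p = 0.429 with an estimated correlation. Of the cholesterol list 8 of 20 fell (8 fell and 1 rose over the list alone), median -0.22, with INSIG1 (-1.64 ± 0.21) and ACAT2 (-1.26 ± 0.13), adjusted p = 0.297 with an estimated correlation. Of 18 heat shock genes 8 fell and 2 rose (8 and 2 over the list alone), median -0.30, with BAG3 at -0.62 ± 0.12, adjusted p = 0.297 with an estimated correlation.

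Cytosolic falls were found in 8 further lists, with medians from -0.27 to -0.12, each lost with an estimated correlation. Of the fatty acid genes 5 of 15 fell (5 over the list alone), with ACLY, the citrate lyase, at -0.93 ± 0.18, adjusted p = 0.0809 with an estimated correlation. Of the purine and pyrimidine genes 7 fell and 1 rose (8 and 1 over the list alone), and 5 of 17 aminoacyl-tRNA synthetases fell (5 over the list alone). Of the ATP synthase subunits 6 of 16 fell (7 over the list alone), with ATP5PF at -0.62 ± 0.14. These 3 lists have adjusted p = 0.429 with an estimated correlation, as do the initiation factors (3 fell and 1 rose, 3 and 0 over the list alone), which are also lost without replicate 3 (0.263). Of the mitochondrial ribosomal proteins 17 of 75 fell and 1 rose (18 and 1 over the list alone), adjusted p = 0.541 with an estimated correlation. Of the proteasome subunits 7 fell and 1 rose (8 and 2 over the list alone), with PSMA2 at -0.84 ± 0.11, adjusted p = 0.479 with an estimated correlation and 0.0505 without replicate 3. Of the complex I subunits 4 fell and 1 rose (4 and 1 over the list alone), adjusted p = 0.653 with an estimated correlation, 0.0620 without replicate 1 and 0.0877 without replicate 3. In replicate numbers 1 to 4 the list mean of mitochondrial ribosomal proteins changed by -0.21, -0.03, -0.47 and 0.01. Proteasome subunits had -0.28, -0.05, -0.55 and 0.02, and complex I -0.28, -0.09, -0.40 and 0.06. These falls thus lie mostly in numbers 1 and 3. The other lists of this paragraph fell in every number.

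Ribosomal protein mRNAs were not called as a list in the cytosol: 1 of 53 rose (0 over the list alone), median 0.05, adjusted p = 0.844. Their list means, 13.09 in vehicle and 13.13 after PP242, also lie high on the scale. Of the other TOP mRNAs 5 fell and 1 rose (5 and 4 over the list alone), adjusted p = 0.644. Of the 7 mitochondrially encoded RNAs 0 passed by limma (0 over the list alone), median -0.18, adjusted p = 0.278. The autophagy list (0.0584, or 0.0335 with the replicate block), the eIF4E-sensitive list (0.193) and ribosome biogenesis (0.135) were not called. The panel had 4 rises and 8 falls among 28 genes. MYC (0.97 ± 0.15), IRS2 (1.06 ± 0.13), SQSTM1 (1.29 ± 0.16) and TXNIP (1.93 ± 0.38) rose, and HIF1A (-0.85 ± 0.17), EIF4E (-0.92 ± 0.14), ASNS (-1.41 ± 0.28), DDIT4 (-1.32 ± 0.32) and LDHA (-0.70 ± 0.11) are among those that fell.

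How far do polysome changes follow cytosolic ones? Of the genes that passed, 1720 passed in both pools, all in the same direction: 873 rose, such as HBEGF (cytosolic 1.77, polysome 1.98), and 847 fell, such as CDK1 (cytosolic -2.23, polysome -2.25). Independent calls would give 115 and 102. Another 924 genes passed on polysomes only, 865 of them with the same sign in the cytosol, and 1533 passed in the cytosol only, 1350 with the same sign on polysomes. Across all genes the effects correlate at 0.73 (Pearson) and 0.54 (Spearman), and at 0.87 and 0.83 over the 4177 genes called in either pool. All 1720 genes are in the abundance mode (2620 with the replicate block, 1017 to 1193 with a replicate left out). The translation mode holds 0 genes and the offset mode 0, since limma called 0 genes for polysome association.

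**Figure D3:**
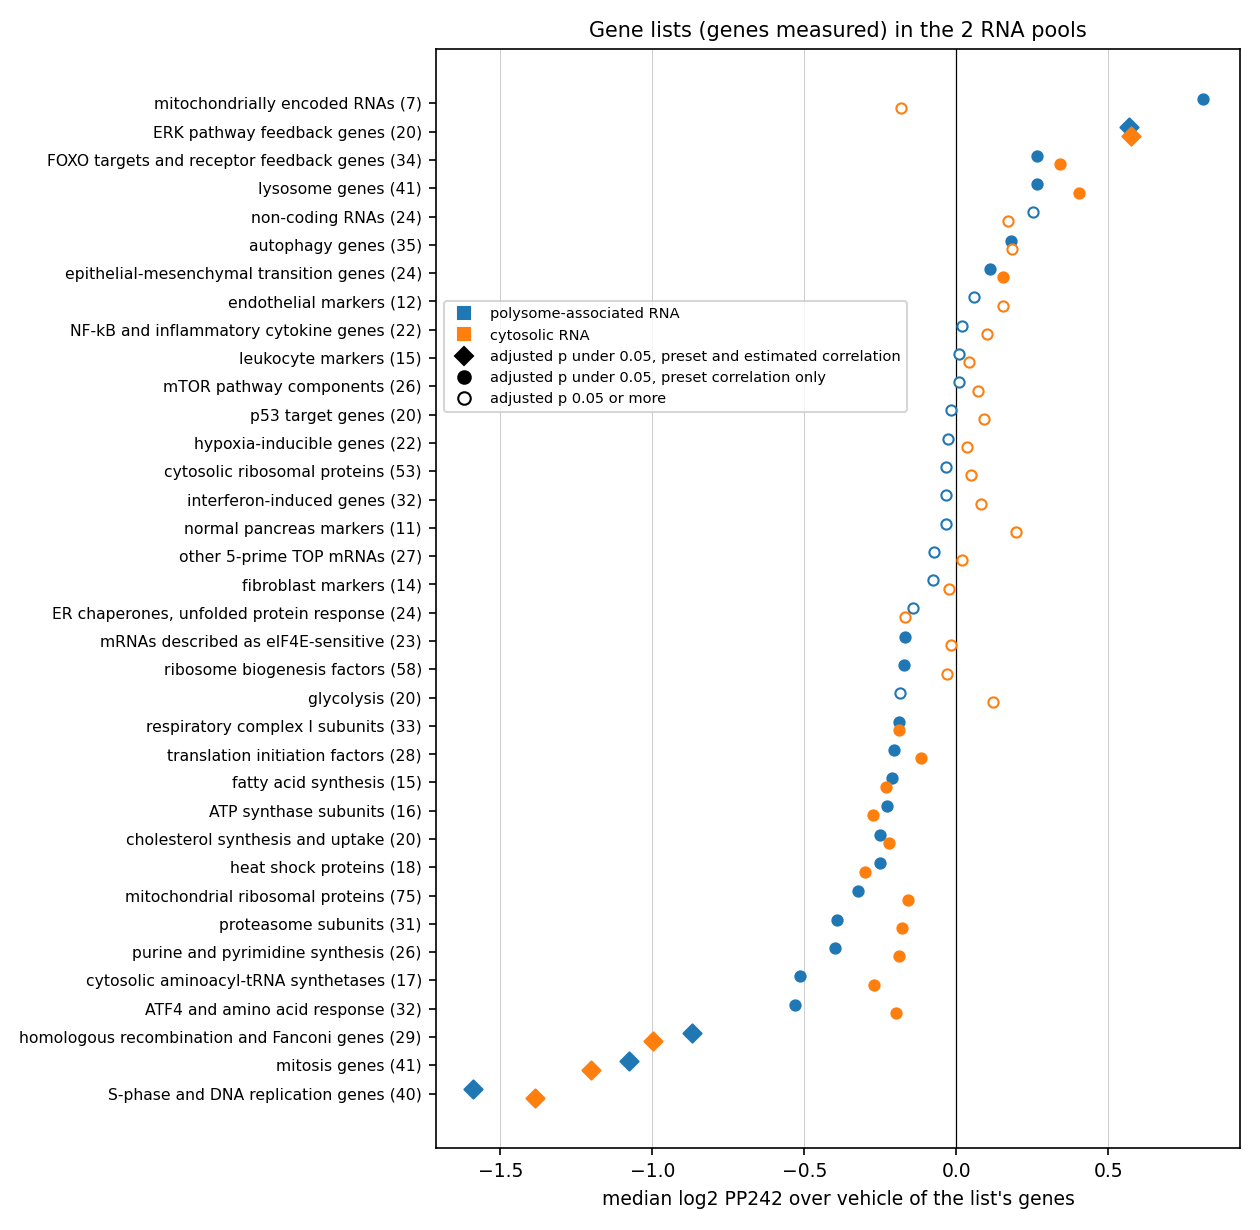
Median log2 change of each gene list in polysome and cytosolic RNA.

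Which mRNAs changed in polysome association beyond their cytosolic change? No gene passed, and ribosomal protein and other TOP mRNAs had medians near that of all genes. The largest panel values were HIF1A at 0.65 ± 0.23 and CCND3 at -0.54 ± 0.18 (n = 4 per group, both adjusted p = 0.558 by limma). EEF2 had 0.32 ± 0.15 (called by the regression of polysome on cytosolic values, 0.30, adjusted p = 0.0254), RPS6 0.05 ± 0.16, EEF1A1 -0.10 ± 0.10 and TPT1 0.14 ± 0.12. Of 53 ribosomal protein genes 36 have a negative sign, with a median of -0.04 (camera adjusted p = 0.772), and the other TOP mRNAs have a median of -0.04 (0.954). Of 23 mRNAs described as eIF4E-sensitive 17 have a negative and 5 a positive sign, with a median of -0.15 (0.647); 0 pass, and 1 is higher over the list alone. The 80 genes of both lists shift by a mean of -0.05 with limits of 2 errors at -0.12 and 0.02, against a median of -0.04 for all genes. Their median level of 13.38 is high on the scale, so compression of bright signals can understate a shift. The closing section takes this up with their dimmer probe sets.

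By limma 0 genes passed for polysome association, with 1750 at an unadjusted p under 0.05 and a smallest adjusted p of 0.4. With the replicate block the count is 0, and with each culture as a block it is 0, with 3032 at an unadjusted p under 0.05 and a smallest adjusted p of 0.0890. The regression of polysome on cytosolic values calls 689 genes (318 higher, 371 lower), of which 448 have a slope between 0 and 1, with a median slope of 0.176. At slopes this low it takes off little of the cytosolic change, so a call can reflect the polysome change alone. CDK1 is called at -3.79 with a slope of -0.686. Its falls in both pools were nonetheless alike, with an adjusted p of 0.983 by limma with each culture as a block. Testing each probe set calls 1, for C4orf46 (1.67 ± 0.22, adjusted p = 0.035), which changed by -0.46 on polysomes and -2.13 in the cytosol. Without cytosolic PP242 array 3, 132 genes pass (120 higher, 12 lower). The groups do not overlap for 1523 genes (7.70%, with 2.86% due to chance). The median error of this contrast is 0.189. Simulated shifts of log2 0.5 were recovered in 4% and of log2 1 in 72% of cases. Smaller shifts in translation thus mostly stay below what the fit without pairing resolves at 4 replicates. The simulated arrays were drawn without pairing of replicate numbers, so these shares do not describe the paired fits.

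Mitochondrially encoded RNAs were called higher in polysome association as a list, at the preset correlation only. All 7 have a positive sign, median 0.98, camera adjusted p = 2.17e-07, while 0 pass singly (5 over the list alone) and adjusted p = 0.298 with an estimated correlation. ND4 has 0.98 ± 0.24, COX2 0.89 ± 0.23 and ATP6 1.34 ± 0.42. Their cytosolic vehicle means (14.27, 14.44 and 14.25) lie near the top of the scale, so a cytosolic rise can be hidden and these shifts are not exact sizes. Their list mean on polysomes went from 10.97 (SD 0.36) to 11.67 (SD 0.47), with PP242 above vehicle in 4 of 4 replicate numbers, and in the cytosol from 12.83 (SD 0.09) to 12.56 (SD 0.38). Non-coding RNAs shifted up by a median of 0.15 (0 pass, 2 over the list alone), with DLEU2 1.20 ± 0.29, CRNDE 1.23 ± 0.34 and NORAD 0.96 ± 0.31, adjusted p = 0.0426 and 0.298 with an estimated correlation. That call is lost without replicate 1 (0.0757) or 4 (0.109). DLEU2 fell in the cytosol (mean 6.137 to 4.215) and on polysomes (4.54 to 3.81), where its signal is low and a fall may be understated. CRNDE also fell in the cytosol (8.845 to 7.395, SD 0.747 after PP242) and on polysomes (8.175 to 7.95). Their upward shifts thus come from larger cytosolic falls, while NORAD rose on polysomes (9.09 to 10.18). Mitochondrial ribosomal proteins shifted by -0.17 (0 pass, 0 over the list alone), with MRPL10 at -0.53 ± 0.19, and purine and pyrimidine genes by -0.21 (0 pass, 0 over the list alone), with PRPS1 at -0.44 ± 0.21 and ATIC at -0.35 ± 0.14. Both have adjusted p = 0.0281 and 0.977 with an estimated correlation, and both are lost without replicate 2 (0.231). The mitochondrial ribosomal call is also lost without replicate 4 (0.265), and its direction turns without cytosolic PP242 arrays 2 and 4 (0.704). The purine and pyrimidine and non-coding calls are lost there too. With the mean of a gene's probe sets the mitochondrial ribosomal (0.220), purine and pyrimidine (0.166) and non-coding (0.220) calls are lost, while mitochondrially encoded RNAs stay called in both runs. With the replicate block lysosome genes (0.0130) and proteasome subunits (0.0218) are added, and fry calls 0 lists. The regression of polysome on cytosolic values, with the limit given above, calls ND4 (1.09, adjusted p = 0.0142), COX1 (0.46, 0.0169) and NORAD (1.17, 0.00809) higher. It does not call COX2 or ATP6. Several mitochondrial ribosomal proteins are called lower by it, such as MRPS2 (-0.56, 0.0223).

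**Figure D4:**
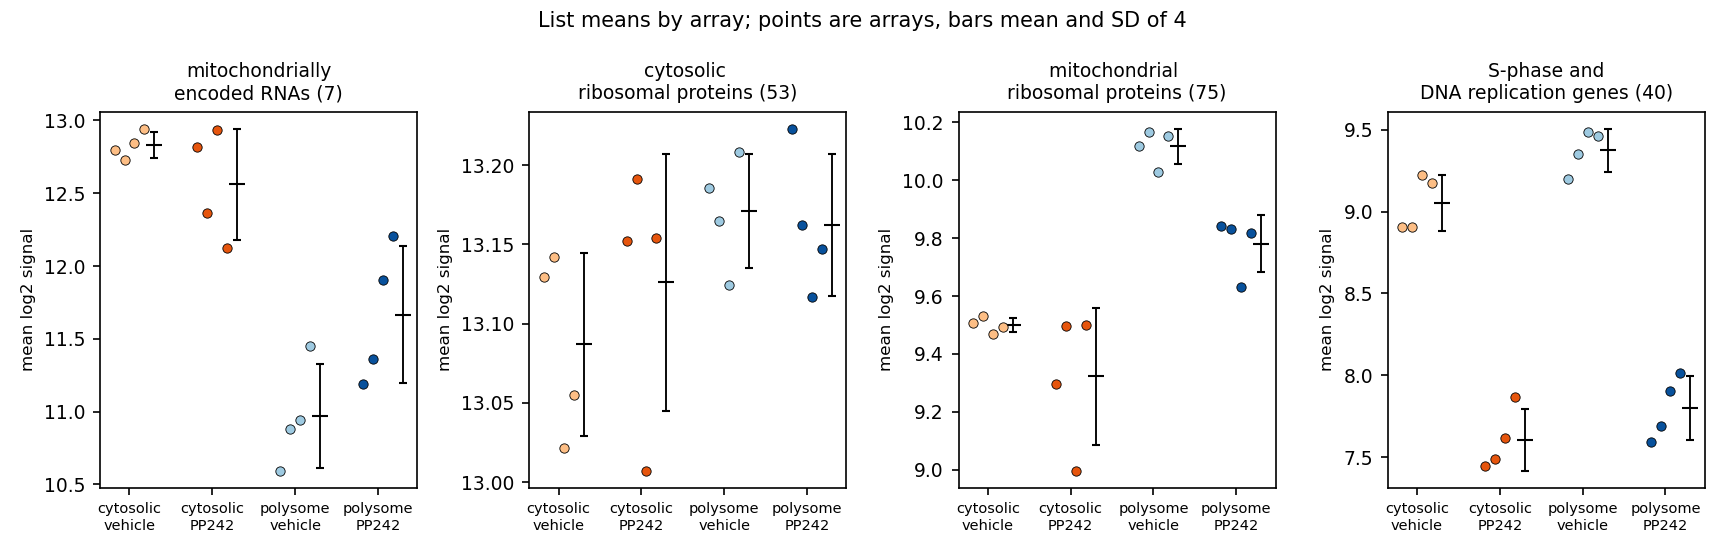
Mean log2 value of 4 gene lists in each of the 16 arrays, with the mean and SD of the 4 arrays of a group.

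How are mRNAs spread over polysomes before treatment? Mitochondrially encoded and non-coding RNAs were scarce on polysomes, and mRNAs of the proteasome, nuclear-encoded complex I subunits and tRNA charging were enriched. ND2 lay -3.70 ± 0.36 and ND4 -2.92 ± 0.17 below cytosolic RNA on the log2 scale (n = 4 per group, limma adjusted p = 2.48e-07 and 1.70e-09). Cytosolic signals of ND4 and ATP6 (14.27 and 14.25) lie near the top of the scale, so their true distance can be larger. ATP6 (-2.32 ± 0.29), LASP1NB (-2.68 ± 0.19), LOC102723847 (-2.50 ± 0.11), ZNF738 (-2.32 ± 0.19), MEGF9 (-2.20 ± 0.13) and the non-coding OIP5-AS1 (-2.17 ± 0.17) follow. Polysome signals of LASP1NB (mean 3.355), LOC102723847 (3.56) and ZNF738 (4.46) lie low on the scale, so their differences are not exact sizes. The most enriched were the chromatin ATPase ATAD2 (2.26 ± 0.22), the transcription factor subunit GTF2F1 (2.19 ± 0.15), TMEFF2 (2.17 ± 0.23), the glutathione synthetase GSS (2.17 ± 0.17) and NUDT1, which cleans oxidized nucleotides (2.15 ± 0.18). UBN1 (2.02 ± 0.15), UBXN4 (1.93 ± 0.14) and the splicing protein SRRM2 (1.84 ± 0.19, but 0.30 and adjusted p = 0.0513 with the mean of its probe sets) come next.

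In this baseline 10432 genes passed, 3327 higher on polysomes (31.9%) and 7105 lower, and 5739 by at least 1.5-fold (1877 higher, 3862 lower). The split depends on scale: with arrays centred on their medians 77.6% of 10947 called genes are higher, with quantile normalization over all arrays 54.1% of 8764, and with cyclic loess 52.7% of 9058. The replicate block gives 11703 genes, numbers 1 and 2 alone 9170, and 3 and 4 alone 6422. The groups do not overlap for 10524 genes (53.2%, with 2.86% due to chance). Baseline values of single genes are as deposited, where the median of all genes is -0.16.

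Proteasome subunits were the most enriched list: 29 of 31 higher (29 over the list alone), median 0.89 against -0.16 for all genes, with PSMA4 1.42 ± 0.11 and PSMB4 1.03 ± 0.08. Aminoacyl-tRNA synthetases (14 of 17 higher, median 0.81), complex I (25 of 33, 0.68, with NDUFB7 1.75 ± 0.15 and NDUFV1 1.67 ± 0.16) and mitochondrial ribosomal proteins (53 of 75, 0.65, with MRPS26 1.49 ± 0.14) follow. Purine and pyrimidine synthesis (17 of 26, 0.64, with MTHFD1 1.66 ± 0.12), ribosome biogenesis (38 of 58, 0.61), ATP synthase (10 of 16, 0.51) and glycolysis (14 of 20, 0.50) come next, all with adjusted p = 0.198 with an estimated correlation. S phase (22 of 40, 0.44, 0.437 with an estimated correlation), lysosome (20 of 41, 0.35, 0.343), initiation factors (12 of 28, 0.33, 0.198) and cholesterol genes (9 of 20, 0.19, 0.198, with FDPS 1.63 ± 0.11) were also called higher. Adjusted over each list alone the 11 lists after the proteasome have 15, 27, 55, 18, 38, 10, 14, 22, 21, 12 and 9 genes higher, in this order. Genes lower number 7 for lysosome, 6 for S phase, 4 for initiation factors, 3 each for cholesterol and ribosome biogenesis, and 2 or fewer for the rest. These 12 lists keep a positive median under all 3 rescalings, but all 12 medians shrink with quantile normalization and with cyclic loess. With cyclic loess proteasome subunits have 0.54 and ATP synthase 0.10 (5 higher, 1 lower). Lysosome genes have 0.10 with quantile normalization (15 higher, 8 lower). Initiation factors have 9 higher and 9 lower with cyclic loess and 9 and 8 with quantile normalization. S phase has 10 higher and 4 lower with quantile normalization.

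For the other lists called higher at baseline the median turns negative or reaches about 0 under some scales. Ribosomal proteins (18 higher and 9 lower of 53, 18 and 8 over the list alone, adjusted p = 0.502 with an estimated correlation) have a median of 0.10 as deposited and 0.51 with centred arrays, against -0.07 with quantile normalization and -0.51 with cyclic loess. RPL27A (0.88 ± 0.11) and RPS9 (0.67 ± 0.11) lie higher as deposited. Other TOP mRNAs (13 higher and 7 lower of 27, with EEF1D 1.43 ± 0.11 and EIF3K 1.02 ± 0.09) have 0.16 as deposited and -0.32 with cyclic loess, adjusted p = 0.198 with an estimated correlation. Mitosis genes (18 higher and 4 lower of 41, 0.212) have 0.24, and 0.65 with centred arrays, 0.09 with cyclic loess (11 higher, 5 lower) and -0.00 with quantile normalization (11 higher, 7 lower). Heat shock genes (10 higher and 2 lower of 18, 0.198, with BAG3 1.45 ± 0.12) have 0.28 and -0.09 with cyclic loess. Endoplasmic reticulum chaperones (10 higher and 7 lower of 24, 0.435, with CRELD2 1.5 ± 0.14) have 0.01 and -0.07 with cyclic loess. The last 4 lists keep their counts when adjusted over the list alone.

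Lower on polysomes under every scale were mitochondrially encoded RNAs (5 of 7 lower, 5 over the list alone, median -1.82) and non-coding RNAs (14 of 24 lower and 1 higher, 14 and 1 over the list alone, median -0.65). With centred arrays non-coding RNAs have 9 lower and 4 higher and a median of -0.24. LINC-PINT (-1.64 ± 0.18) and EMX2OS (-1.48 ± 0.10) are examples. Their adjusted p = 0.343 and 0.198 with an estimated correlation. The interferon list is added with the replicate block (0.0495). Among panel genes 7 lay higher and 8 lower, with TFAM at 1.08 ± 0.13 (-0.028 with the mean of its probe sets), CCND1 0.89 ± 0.18 (0.31 and adjusted p = 0.164 with the mean of its probe sets), IRS2 -1.19 ± 0.13, EIF4E -1.01 ± 0.14 and MCL1 -0.97 ± 0.18.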

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

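The tests of carry-over in the polysome arrays, of a cytosolic rise hidden near the top of the scale and of a stronger response in 2 cultures, and the reading of splits by how evenly they mix the groups, were chosen only after the results they measure had been seen. Mitochondrially encoded RNAs were called higher in polysome association after PP242 as a list, with a median difference between polysome and cytosolic effects of 0.98. Singly 0 of them passed by limma, and the list call by camera is lost with an estimated correlation. Noise of cytosolic PP242 arrays 2 and 4 is argued against, since the median stays at 0.775 without both arrays. Carry-over of mitochondria in single polysome arrays stays open: the lowest PP242 array lies at -0.26 relative to the highest vehicle array, so the array means of the 7 RNAs overlap, while within replicate numbers PP242 lies above vehicle in 4 of 4 pairs by 0.48 to 0.96, which goes against carry-over in only 1 or 2 arrays. Higher carry-over in all polysome PP242 arrays was not tested and stays open as well. A smaller share of translated mRNA on PP242 polysomes, which would lift every poorly loaded RNA, cannot be told apart, because the 1186 brighter genes with the lowest loading shifted by a median of 0.15 and 0.205 above that of all brighter genes in the 2 cross-fitted runs, and only 1 of them reaches the 0.2 set beforehand. A cytosolic rise hidden by signal near the top of the scale cannot be told apart either, because only 2 of the 7 RNAs have a cytosolic mean under 12, with a mean shift of 1.04 and an error of 0.493; an effect of PP242 on mitochondrial translation stays among the open explanations, as untested.

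Ribosomal protein and other 5-prime TOP mRNAs showed no shift in polysome association: 80 genes, mean -0.05, error 0.037. Compression of bright probe sets as the whole cause is argued against by their 39 probe sets between 7 and 11, which shift by 0.037 with limits of -0.07 and 0.15. That holds only if these dimmer probe sets follow the same mRNAs, which was not tested. Noise of cytosolic PP242 arrays 2 and 4 is argued against as well, with a median of -0.014 without both. A fall shared by all mRNAs and removed by the normalization cannot be told apart, since the median of all genes is -0.04 by construction of the scale. A true lack of change on more than 3 ribosomes is untested, and a loss inside that pool, from many to fewer ribosomes, would not show.

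Cytosolic PP242 arrays 2 and 4 stood apart from arrays 1 and 3 by array weight, but array 3 has a larger mean absolute deviation (0.214) than array 2 (0.193), and leaving out array 3 alone gives 132 genes for polysome association, against 0 without array 2, array 4 or both. A stronger response of those cultures is argued against by the deviations of the 2 arrays, which correlate at 0.061 with those of the matching polysome arrays. Nuclear RNA in arrays 2 and 4 is argued against by the mean deviation of 3 nuclear RNAs from their group mean. It is -0.43 in array 2 and -0.40 in array 4, against -0.10 in array 1 and 0.94 in array 3. The high value of array 3 lowers the other deviations, but arrays 2 and 4 also lie below array 1. An intensity-dependent normalization error is argued against because 95.8% of the deviation is left after cyclic loess. Causes for array 3, and a difference between the cultures other than a stronger response, were not tested.

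Other splits of the 8 arrays or cultures into 4 and 4 were run, 35 in all with the real one. Polysome, cytosolic and baseline counts relabel the arrays of 1 comparison, while the abundance mode, polysome association and the correlation relabel both pools together. Over all 35 splits only the real one reached the counts of genes called on polysomes (2644 against at most 89) and in the cytosol (3253 against 1). The same held at baseline (10432 against 5) and in the abundance mode (1720 against 98). It also held at an unadjusted p under 0.05 for polysome association (1750 against 1148). This count ignores the pairing of replicate numbers, so by itself it does not exclude chance. The highest other counts of called genes all come from the split of numbers 1 and 2 from 3 and 4. In every other split the real difference enters the spread within the relabelled groups, which lowers the counts of called genes. The gaps to the real counts are thus partly built in and do not by themselves exclude chance. For the 0 genes called for polysome association all 35 splits gave as many. The real split also had the highest correlation of effects (0.728 against 0.721) and the most lists called on polysomes (22 against 19), by small margins. By the count over all 35 splits chance cannot be excluded for the lists called in the cytosol (18 against 20, with 5 splits as large). Nor can it for polysome association (4 against 6, with 5 splits as large) or at baseline (19 against 20, with 2 splits as large). Of the other splits, 16 keep 3 of the 4 arrays of a real group together and so hold part of the real difference. They include the 4 other splits as large in the cytosol and the 1 at baseline, and 2 of those as large for association. The 18 splits that mix the groups evenly gave at most 9 lists on polysomes, 13 in the cytosol, 6 for association and 15 at baseline, and a correlation of at most 0.614. Only for association is the real value (4 lists) reached by an even mix. The 7 other splits that part all 4 replicate pairs, as the real one does, gave at most 0 called genes in each contrast and mode, 564 genes at the unadjusted threshold, a correlation of 0.691, and 19, 20, 4 and 18 lists on polysomes, in the cytosol, for association and at baseline. These splits are too few for a share under 0.05.

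Differences between the polysome and the cytosolic effect drew attention for mitochondrial ribosomal proteins (median difference -0.17), purine and pyrimidine synthesis (-0.21), non-coding RNAs (0.15) and mitochondrially encoded RNAs (0.98), each by camera on the interaction, and for a probe set of C4orf46 (1.67). Probe sets without a single gene name, 13522 in number, hold signal too: 504 passed on polysomes (313 higher, 191 lower), 731 in the cytosol (438 higher, 293 lower) and 6140 at baseline (886 higher, 5254 lower).

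Single arrays far from the other 3 of their group were searched with Dixon's ratio of gap to range, over 140 genes, 36 list means and 2 array measures. Of 712 groups of values 29 stood out (4.07%), and chance flags about 1 in 20 groups. In polysome PP242 these were CCNA2 (ratio 1, 8.31 against 8.32 in the others), CCND1 (0.871, 8.4 against 8.94 to 9.02), EGR1 (0.958, 10.33 against 9.85 to 9.87), TFAM (0.938, 10.65 against 10.17 to 10.20), SRRM2 (0.860), MTHFD1 (0.857), PSMB4 (0.833), RFC4 (0.833) and RPS9 (0.833). List means there were mitochondrial ribosomal proteins (0.885, array 3), hypoxia-inducible genes (0.847, array 1) and purine and pyrimidine synthesis (0.851, array 4). In polysome vehicle they were KLF6 (0.882), PRPS1 (0.875), MRPL10 (0.867), EXO1 (0.857), GINS2 (0.844) and the list means of ERK feedback (0.956, array 3) and purine and pyrimidine synthesis (0.841, array 1). In cytosolic PP242 they were MYC (0.907, 10.80 against 11.29 to 11.34), PAICS (0.885), MEGF9 (0.837) and the mean of non-coding RNAs (0.830, array 3). In cytosolic vehicle they were PSMB4 (1), PCNA (0.923), EPHA4 (0.897), RFC4 (0.846), the mean absolute deviation (0.850, array 1) and the median of all probe sets (1, 5.01 against 5).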

How the results depend on the processing

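The alternatives were fixed before the values were seen, except the batch block, the runs on replicate numbers 1 and 2 or 3 and 4 alone, and the runs without cytosolic PP242 arrays 2 and 4, which were chosen after. In polysome RNA the count of 2644 becomes 4020 with the replicate block, 1089 with numbers 3 and 4 alone, 1589 at 1.5-fold, 4480 by probe set, and 1627 to 2445 with 1 array or number left out. In cytosolic RNA 3253 becomes 4929 with the block, 1058 with numbers 3 and 4 alone, 1976 without cytosolic PP242 arrays 2 and 4, 1837 at 1.5-fold, 5529 by probe set, 2069 with only the 8 arrays, and 1543 to 4520 in the leave-out runs. Polysome association goes from 0 to 1 with the mean of a gene's probe sets, 1 by probe set, 689 by regression, and 0 to 132 in the leave-out runs. The baseline goes from 10432 to 6700 without dim genes, 6422 with numbers 3 and 4 alone, 5739 at 1.5-fold, 26566 by probe set, and 8617 to 9772 in the leave-out runs. The abundance mode goes from 1720 to 2633 at an adjusted p under 0.15, 2620 with the block, and 1017 to 1193 in the leave-out runs. With an estimated correlation 4 lists are called on polysomes, 4 in the cytosol, 0 for association and 0 at baseline. Association lists go from 4 to 0 by fry, 7 without dim genes, 1 with the mean of probe sets, 11 with numbers 1 and 2 alone, 2 with 3 and 4 alone, 2 without cytosolic PP242 arrays 2 and 4, and 2 to 8 with a number left out. The correlation of effects goes from 0.728 to 0.866 over called genes, 0.863 without cytosolic PP242 arrays 2 and 4, and 0.644 to 0.764 with a number left out. Directions turned for mitochondrial ribosomal proteins in association without cytosolic PP242 arrays 2 and 4 (adjusted p = 0.704), for FARSB on polysomes (0.02) and CCND3 (-0.019) and TFAM (-0.028) at baseline with the mean of probe sets, and for EEF1A1 (0.39) and TPT1 (0.355) at baseline with centred arrays. Among lists and named genes the block added the non-coding RNA list on polysomes, autophagy in the cytosol, lysosome and proteasome in association and interferon at baseline, and 13 results of named genes; it changed no other call. The cause was not tested. Without the 40% dimmest genes the correlation of effects is 0.77.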

Other observations

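All gene families in this part were chosen only after the values had been seen. The inhibitor-of-DNA-binding genes, which hold back helix-loop-helix transcription factors, mostly fell: ID1 by -1.73 ± 0.20 on polysomes and -1.35 ± 0.20 in the cytosol, ID2 by -2.71 and -2.96, and ID3 by -2.12 ± 0.20 and -1.89 ± 0.20 (SE, n = 4 per group, limma), while ID4 did not pass. The atypical repressors E2F7 (-1.71 ± 0.21 and -1.70 ± 0.21) and E2F8 (-2.43 and -2.59) and the activator E2F2 (-1.52 ± 0.18 and -1.53 ± 0.18) fell in both pools. E2F1 passed in the cytosol (-0.57 ± 0.18) and not on polysomes (-0.42 ± 0.18), with no difference called between the pools (adjusted p = 0.867). Of 8 E2F genes 3 fell on polysomes and 4 in the cytosol.

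Some genes of pericellular proteolysis rose. The protease urokinase PLAU rose by 1.13 ± 0.11 on polysomes and 1.43 ± 0.11 in the cytosol, and its receptor PLAUR by 1.58 ± 0.12 and 1.82 ± 0.12, while PLAT did not pass. The collagenase MMP1 rose by 0.84 ± 0.16 and 0.81 ± 0.16 beside MMP10, and 4 of 6 collagenases and stromelysins did not pass. The AP-1 subunit JUN rose by 1.00 ± 0.15 and 0.93 ± 0.15, and of 7 AP-1 subunits 2 were higher on polysomes and 1 in the cytosol. The EGF receptor ligand BTC passed on polysomes (1.13 ± 0.31, adjusted p = 0.0194) and not in the cytosol (0.24 ± 0.31), with no difference called between the pools (adjusted p = 0.560 by limma); the regression of polysome on cytosolic values calls it at 0.95, with an adjusted p just under 0.05.

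At baseline, zinc finger genes with ZNF symbols lay low on polysomes: 255 of 502 lower and 28 higher, median -0.37 against -0.16 for all genes. Quantile normalization gives 147 lower and 68 higher, cyclic loess 153 and 65, and centred arrays 118 and 134, and adjusted p = 0.244 with an estimated correlation. After PP242 51 rose and 10 fell on polysomes (camera adjusted p = 3.27e-04, 0.0709 with an estimated correlation). In polysome association 0 passed, with a median of 0.07 against -0.04 for all genes (4.93e-04, 0.235 with an estimated correlation).

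Replicate numbers 1 and 2 differ from 3 and 4 in all groups, with 3186 genes passing, 2025 higher and 1161 lower in 1 and 2. Interferon-induced genes carry the largest list difference: 23 of 32 are higher in numbers 1 and 2, median 0.69, camera adjusted p = 5.90e-23 and 0.00173 with an estimated correlation. OASL (1.81), IFIT1 (1.30), IFI6 (1.27) and ISG15 (1.16) are among them. The list mean differs by 0.65 in cytosolic vehicle, 0.82 in polysome vehicle, 0.65 in cytosolic PP242 and 0.68 in polysome PP242. Of the S-phase genes 20 of 40 are lower in numbers 1 and 2 (median -0.26, 0.0981 with an estimated correlation). This contrast lies across the treatment groups and was chosen after the arrays had been seen.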
